A study of Mus musculus with 9 samples.

How the data were processed

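Poly-A RNA was sequenced from 9 libraries of mouse oviduct tissue: 5 normal oviducts (3 Dicer1+/D1693N and 2 Dicer1+/+) and 4 primary Dicer1ko/D1693N tumors. Per the labels, total RNA was extracted with a miRNeasy kit, and mRNA was purified on oligo-T beads and primed with random hexamers. The submitters name FastQC 0.11.5, STAR 2.5.3a and HTSeq (version not given) with the genome build GRCm38 (mm10). The strandedness and the annotation used for counting are not stated.

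The deposited table holds 19435 genes and 9 libraries on a log2 scale, and its transformation is not stated. All 9 columns share a floor of 3.427, held by genes without a read. The values were checked against the closed form of a variance-stabilizing transformation of negative binomial counts with a parametric dispersion trend. Undoing it gave whole reads divided by a size factor per library, for 100% of values at a tolerance of 0.05 reads. Read totals, size factors and normalized counts were recovered this way, and every gene kept by the authors had at least 10 reads in total. A difference on this scale understates the change of a gene with few reads. Totals were 8504993 to 12526078 reads per library. A floor of 3 counts per library corresponds to at most 3.35 normalized counts in an oviduct and at most 3.41 in a tumor, and these highest values were used. Where all libraries of a group had 0 reads, the fold change is given as a bound against this floor, which covers counting error only, since reads without molecular identifiers are not independent molecules.

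Symbols were matched to GENCODE M21, the GRCm38 annotation. Of the symbols, 18576 matched directly and 620 through an older symbol, together 98.8% of the table, and 239 did not match. The table holds 25 symbols that look like dates, which were not matched, and 7 symbols that occur more than once (20 entries).

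Groups were taken from the labels. The 4 comparisons were tumor against oviduct in a 2-group model, and tumor against Dicer1+/D1693N oviduct, tumor against Dicer1+/+ oviduct and Dicer1+/D1693N against Dicer1+/+ oviduct in a 3-group model in which all 9 libraries share 1 spread. Each was tested on the deposited log2 values by limma 3.58.1 in R 4.3.3 (moderated test with a trend in the prior variance, two-sided), with Benjamini-Hochberg adjustment over 19435 genes. A gene was called at an adjusted p under 0.05 with an absolute log2 change of at least 1. Nothing in the labels pairs oviducts with tumors. Deviations from the group means of libraries with the same number correlated at 0.117, 0.061, -0.089 and 0.006, within the range of the other pairs, so no pairing was used. No batch is given in the labels. On 200 simulated changes of 2-, 4- and 16-fold the tumor against oviduct test called 16.4%, 77.6% and 95.5% of them, with 7.4% false calls. The test of the oviduct genotypes called 6.0%, 40.3% and 83.3%, with 6.5% false calls. Each simulation changed 200 of 19435 genes, none near the floor, with 1 spread per gene for both groups. In the data 3625 genes were called between tumors and oviducts, and the tumors varied more. The rates therefore do not give the sensitivity of the real tests.

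The 26 gene lists were written before the data were examined: miRNA machinery, let-7 targets and oncofetal genes, imprinted growth genes, secretory and ciliated epithelium, smooth muscle, skeletal muscle, cartilage, bone, neural, proliferation, Müllerian and steroid receptor, mesenchymal, collagen and matrix, T and NK cells, B and plasma cells, macrophages, endothelium, fat cells, ovarian steroid, oocyte, mesothelium, red cells, hypoxia and glycolysis, immediate early and dissociation response, and p53 and cell cycle inhibitors. They were tested with camera (correlation 0.01, two-sided), with camera at the estimated correlation and with fry, each adjusted over the 26 lists. Fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Named genes also followed a rule written before the data were examined. For tumor against oviduct these were the 12 largest rises and 12 largest falls among called genes without overlap between groups and with a group mean in the upper part of the table, up to 4 called members of each list per direction, and a fixed set (among them Dicer1, Hmga2, Lin28b, H19, Igf2, Mki67, Foxj1, Ovgp1, Epcam and Trp53). For the other comparisons they were the 5 largest called changes per direction. Values of Myh3, Adipoq, Hbb-bs and the Hox genes outside the lists, and the miR-29, miR-200b and miR-200c and miR-21 results, were singled out after their values were seen.

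For miRNA sites, the longest annotated 3' UTR of at least 50 bases was taken for 16332 genes. The log2 change was regressed on the presence of a 7-base site matching miRNA bases 2 to 8, with log2 UTR length and GC content as terms, for 27 families and for all 16049 7-mers found in at least 100 genes. Families of 5p and 3p strands were compared by a two-sided permutation test with 100000 permutations. On simulated data with a planted shift of 0.3, the estimate was 0.287 ± 0.029.

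Alternatives fixed in advance were other pseudocounts, only the 14576 genes with the higher means, median centring, quantile normalization, moderation without trend or robust, array weights, no minimum change, a block by replicate number, 1 control genotype at a time, leaving out each library, and for miRNA sites the number of sites, expressed genes alone and no UTR terms. Added after seeing the data were limma-voom on recovered reads, log2(normalized count + 1), the 5 oviducts alone, leaving out tumors 1 and 4 (more than 2000 normalized counts of Hbb-bs or Adipoq), and leaving out each library for miRNA sites. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.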

Results

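Messenger RNA was sequenced from 5 normal mouse oviducts and 4 primary tumors of the mouse oviduct. Oviducts 1 to 3 were Dicer1+/D1693N, oviducts 4 and 5 were Dicer1+/+, and the tumors were Dicer1ko/D1693N, with D1693N as the remaining Dicer1 allele. DICER1 is the RNase III enzyme that cleaves miRNA precursors. D1693N lies in its RNase IIIb domain, which frees the 5p strand of the precursor. The table held 19435 genes. The 5 oviduct libraries held 8504993 to 12526078 counted reads and the 4 tumor libraries 8732190 to 11267144. The oviducts had 731 ± 134 genes without a read and the tumors 1971 ± 762. Library pairs correlated across genes at 0.968 to 0.986 among the oviducts and at 0.864 to 0.929 among the tumors, so the tumors varied more. Values below are counts normalized with the size factors held in the deposited values, as mean ± SD, and changes are differences of the deposited log2 values, tumor minus oviduct, ± SE.

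The comparison of tumors with oviducts asks how the transcriptome of Dicer1 mutant tumors differs from that of the normal organ. The tumors had low levels of the ciliary genes of the oviduct and high levels of cell cycle genes and of some collagen, oncofetal and posterior Hox genes. Foxj1, the regulator of motile cilia, stood at 5375 ± 1100 normalized counts in the oviducts (n = 5) and at 83.0 ± 109 in the tumors (n = 4). Mki67, a gene of dividing cells, rose from 129 ± 35.3 to 1435 ± 501. Hmga2, a chromatin protein of embryonic tissue and a known let-7 target, rose from 85.6 ± 23.0 to 2385 ± 1831. Over all genes, 1269 were called higher and 2356 lower in the tumors, at an adjusted p under 0.05 with a log2 change of at least 1. Of these 3625 genes, 3084 had tumors and oviducts that did not overlap. Such separation was seen in 27.6% of all genes, where chance gives 1.59%. Quantile normalization moved the median change of all genes from -0.048 to 0.078 (log2) and gave 1696 higher and 1943 lower genes. With the 2 Dicer1+/+ oviducts alone as controls the counts were 358 and 1178, and without the minimum change of log2 1 they were 2446 and 3605.

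Dicer1 (ENSMUSG00000041415.10, GRCm38 chromosome 12, 104687742 to 104751952, minus strand) held 1086 ± 131 normalized counts in the oviducts and 995 ± 396 in the tumors, a change of -0.21 ± 0.25 (adjusted p = 0.568). The tumors ranged from 576.3 in tumor 4 to 1379.2 in tumor 3, and without tumor 4 the change was 0.02. Gene-level counts do not tell the knockout and D1693N alleles apart. Of the 20 genes of the miRNA machinery list, among them Drosha, Dgcr8 and the Argonautes, 0 were called, also when adjusted over the list alone (camera adjusted p = 0.254, median change 0.03). By limma with an adjusted p alone, 3 of the 20 passed.

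**Figure D1:**
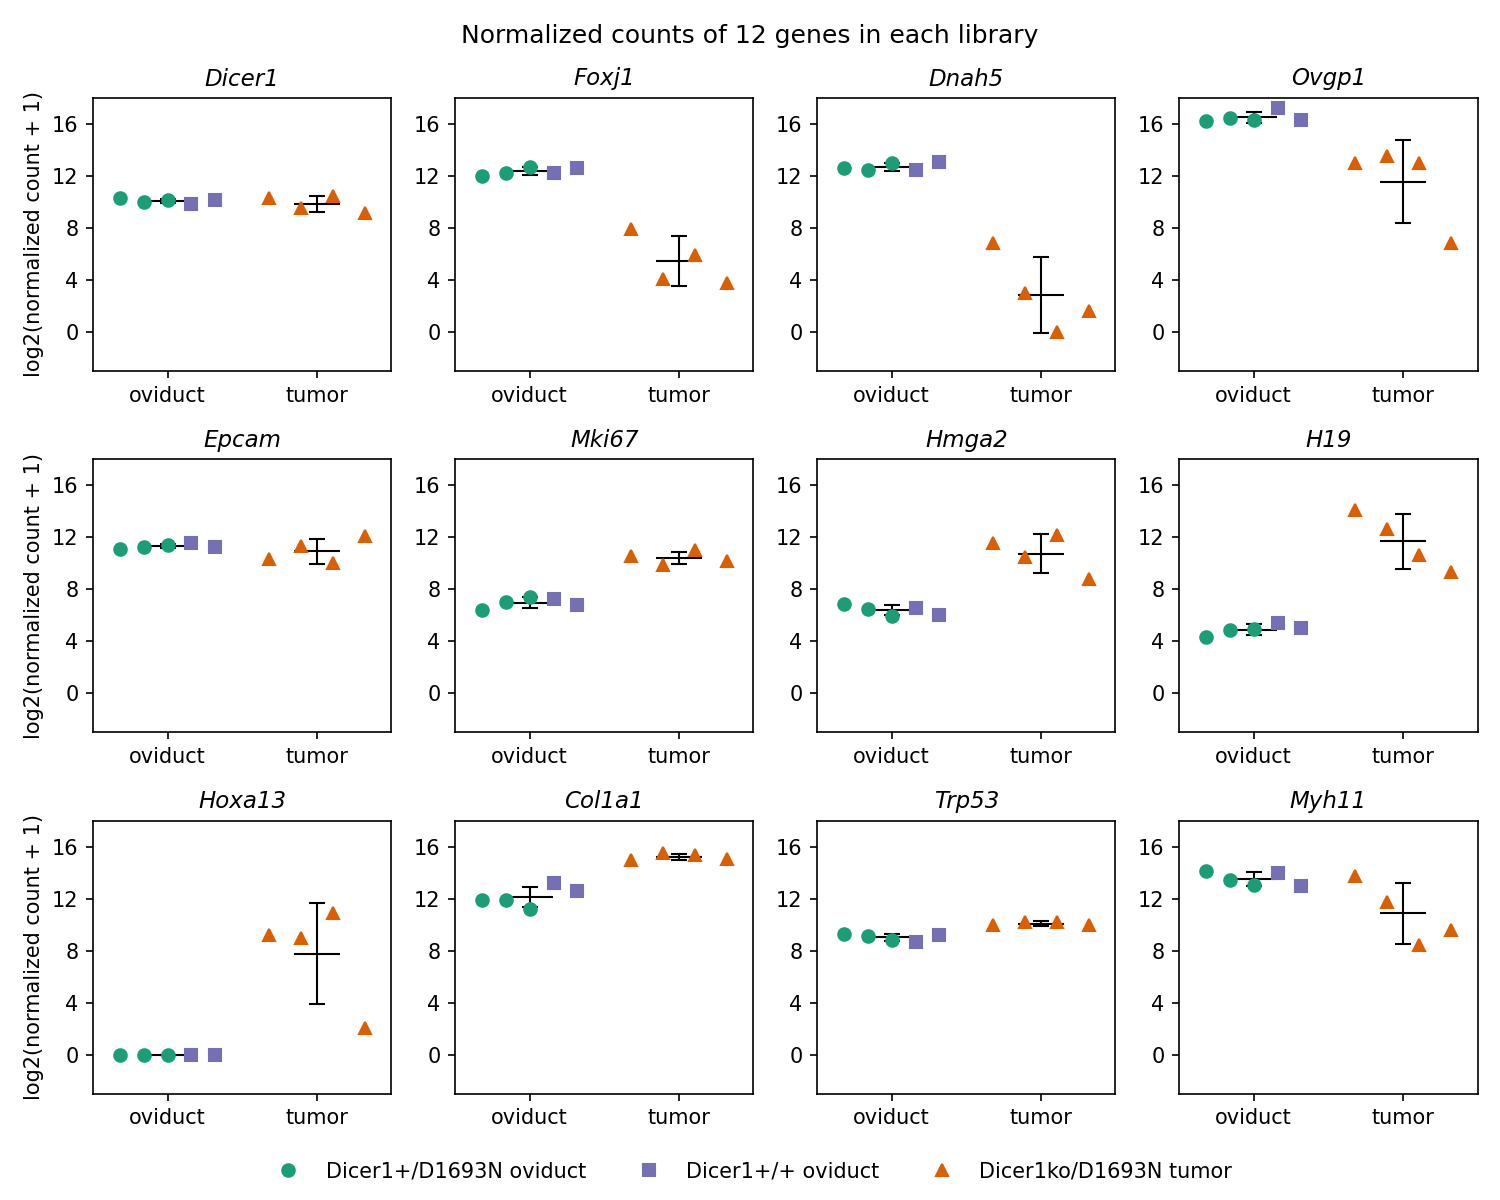
Normalized counts of 12 genes in each library, as log2(normalized count + 1), with circles for Dicer1+/D1693N oviducts, squares for Dicer1+/+ oviducts and triangles for tumors. Black bars are the mean ± SD of the plotted values per group (n = 5 oviducts, n = 4 tumors). Foxj1 and Dnah5 are lower in all 4 tumors than in any oviduct and Mki67, Hmga2, H19, Col1a1 and Trp53 are higher, while Dicer1 and Epcam overlap. Ovgp1 is lowest and Hoxa13 near 0 in tumor 4.

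The genes of ciliated cells fell as a group. Of 31 measured genes of the ciliated epithelium list, 29 fell and 0 rose, with the same counts when adjusted over the list alone, and the median change was -4.99. Dnah5, a heavy chain of the dynein arm that moves cilia, fell from 6812 ± 1458 to 30.1 ± 54.4 normalized counts (-7.94 ± 0.59, adjusted p = 6.83e-06). Foxj1 changed by -6.28 ± 0.54 (adjusted p = 1.69e-05), and Ccdc153 by -7.50 ± 0.57. Dnah3, Dnah6, Dnah9, Dnah12, Rsph4a, Cdhr3, Ttc21a, Lrrc74b and Ccdc108 were also among the 12 largest falls, with changes from -6.71 to -7.49. Sec14l3 showed the largest fall of the genes singled out, from 3005 ± 746 to 0.243 ± 0.486. Camera gave the list an adjusted p of 9.4e-21, fry 2.45e-05, and the adjusted p was 0.176 with an estimated correlation. Tumor 1 kept some of this signal, with 111.7 normalized counts of Dnah5 against 0 to 6.8 in the other tumors.

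Genes of epithelial cells in general changed less and in both directions. Of 29 measured genes of the secretory epithelium list, 3 rose and 6 fell (4 and 6 adjusted over the list alone), and the median change was -0.38. The list did not pass (camera adjusted p = 0.254, fry 0.281) except under quantile normalization (0.0318) and without tumor 4 (0.0225). Ovgp1, the oviduct-specific glycoprotein of secretory cells, fell by 4.88 ± 1.13 on the log2 scale, from 96343 ± 30655 to 6981 ± 4886 (adjusted p = 0.00857). In tumor 4 it was at 111.5, against 8061.2 to 11678.2 in the other tumors. Ehf, an epithelial transcription factor, fell by 1.63 ± 0.12. Cldn4, which codes for a tight junction protein, rose by 2.07 ± 0.51, and Wfdc2 rose by 1.64 ± 0.28. Epcam was at 2577 ± 309 in the oviducts and 2314 ± 1526 in the tumors (adjusted p = 0.464), and without tumor 4 its change was -0.76 rather than -0.38 (adjusted p = 0.0494). Pax8, a Müllerian lineage factor, was at 1388 ± 230 and 864 ± 338 (adjusted p = 0.0602, 0.0274 without tumor 2 and 0.0492 under quantile normalization).

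Cell cycle genes rose almost without exception: 36 of the 38 genes of the proliferation list, also adjusted over the list alone, with a median change of 2.51. Top2a rose by 3.39 ± 0.25 (adjusted p = 6.55e-06), Mki67 by 3.25 ± 0.26, Ccnb1 by 3.46 ± 0.34 and Ccne1 by 3.32 ± 0.32. Camera gave an adjusted p of 1.16e-28 and fry 1.54e-05, and the adjusted p was 0.175 with an estimated correlation. In the p53 and cell cycle inhibitor list 8 of 16 genes rose, also adjusted over the list alone, and 0 fell (camera adjusted p = 0.000142, fry 0.00098, adjusted p = 0.206 with an estimated correlation). Trp53 rose from 531 ± 90.5 to 1111 ± 121, Cdkn2a, which codes for p16 and p19ARF, from 42.9 ± 31.1 to 528 ± 271, and Cdkn1a, which codes for p21, from 495 ± 65.8 to 1680 ± 1021. Pmaip1, a proapoptotic p53 target, rose by 3.42 ± 0.36.

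Some oncofetal and imprinted growth genes were higher in the tumors. Of the 40 genes of the let-7 target and oncofetal list, 17 rose and 0 fell, with the same counts adjusted over the list alone and a median change of 0.83 (camera adjusted p = 3.5e-07, fry 0.00107, adjusted p = 0.176 with an estimated correlation). Hmga2 rose by 4.08 ± 0.56 (adjusted p = 0.000361) and Igf2bp2, an mRNA-binding protein of embryonic tissue, by 2.48 ± 0.32 (adjusted p = 0.000243). Trim71, a let-7 target of embryonic cells, had no read in the oviducts and 103.7 ± 66.8 normalized counts in the tumors, at least 31.0-fold higher than the floor of 3 counts per library. Igf2bp1 rose by 2.22 ± 0.69 (adjusted p = 0.033), a call lost without any 1 of the 5 oviducts (adjusted p up to 0.0666). Lin28b, which blocks let-7 maturation, had no read in the oviducts and reached 538.0 in tumor 1, with 0.0 to 4.5 in the other tumors (adjusted p = 0.176). Igf2bp3 was at 409.8 in tumor 1 and at 23.8 to 26.3 in the others, against 27.8 ± 4.84 in the oviducts (adjusted p = 0.406), and without tumor 1 its change was -0.09.

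Of the 22 imprinted genes, 11 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000311, fry 0.0539, adjusted p = 0.518 with an estimated correlation). H19, the maternally expressed noncoding RNA beside Igf2, rose from 30.1 ± 8.14 to 6622 ± 7872 (6.11 ± 0.77, adjusted p = 0.00022). Igf2, a fetal growth factor, rose by 3.58 ± 0.82 (adjusted p = 0.00811), and Mest by 4.15 ± 0.88. Igf2 stood at 217.7 and Mest at 204.0 normalized counts in tumor 4, and Igf2 in tumor 4 lay within the range of the oviducts. Dlk1 rose by 4.64 ± 1.57 (adjusted p = 0.0463), from 15.8 ± 11.1 to 5557 ± 9633. It was at 19984 in tumor 1 and 1.1 in tumor 4, and its call was lost without any 1 of the 5 oviducts or tumors 1, 2 or 3 (adjusted p up to 0.101) and with limma-voom (0.436). Zdbf2 fell by 1.65 ± 0.29.

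The called genes of the extracellular matrix and of mesenchymal cells were all higher, while the called smooth muscle and mesothelial genes were all lower. In the collagen and matrix list 21 of 33 genes rose and 0 fell, also adjusted over the list alone, with a median change of 1.959 (camera adjusted p = 7.48e-13, fry 0.000226, adjusted p = 0.176 with an estimated correlation). Col1a1, the main chain of type I collagen, rose from 5156 ± 2780 to 38964 ± 6771. Tnc, a matrix glycoprotein of developing and wounded tissue, rose by 4.22 ± 0.36 (adjusted p = 1.53e-05), Fbn2 by 4.21 ± 0.54 and Mmp2, a matrix metalloproteinase, by 3.54 ± 0.27. In the mesenchymal list 9 of 23 genes rose and 0 fell, and adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 0.000142, fry 0.00135, adjusted p = 0.176 with an estimated correlation). Cdh11 rose by 3.05 ± 0.34, Snai1 by 2.18 ± 0.31 and Snai2 by 1.81 ± 0.48.

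Of 22 smooth muscle genes 8 fell (9 adjusted over the list alone) and 0 rose (camera adjusted p = 0.000927, fry 0.0273, adjusted p = 0.545 with an estimated correlation). The list mean (log2) of tumor 1, 9.374, lay within the range of the oviducts, 9.241 to 10.057, and the other tumors had 7.027 to 8.504. Synm, which codes for an intermediate filament protein, fell by 3.82 ± 0.46, Kcnmb1 fell by 2.95 ± 0.39 and Pln fell by 2.69 ± 0.26. Myh11, the smooth muscle myosin, fell by 2.60 ± 0.87 (adjusted p = 0.0432). It kept 13837 normalized counts in tumor 1, and its call was lost without any 1 of the 5 oviducts or tumors 2, 3 or 4 (adjusted p up to 0.0924). Of 11 mesothelial genes 8 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.000142, fry 0.00107, adjusted p = 0.286 with an estimated correlation). Gpm6a fell by 3.13 ± 0.40, and Wt1 fell from 2383 ± 127 to 597 ± 647.

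Several posterior Hox genes, which pattern the lower genital tract, were higher in tumors 1 to 3 than in every oviduct: Hoxa10, Hoxa11, Hoxa13 and Hoxd13. Hoxa13 and Hoxd13 had no read in any oviduct. Their means in the tumors were 760 ± 826 and 881 ± 1352 normalized counts, at least 226.9-fold and 263.2-fold higher than the floor of 3 counts per library, and at least 110.0-fold and 63.9-fold without tumor 3. Hoxa13 stood at 595.3, 506.5 and 1935.4 in tumors 1, 2 and 3 and at 3.2 in tumor 4. Hoxd13 stood at 505.0, 137.4 and 2883.3 in those tumors and at 0.0 in tumor 4. Hoxa10 and Hoxa11 rose by 2.74 ± 0.52 and 3.43 ± 0.80. In tumor 4 Hoxa10 stood at 189.3, also above every oviduct (at most 122.0), and Hoxa11 at 24.2, within the range of the oviducts. With limma-voom the adjusted p was 0.109 for Hoxa13, 0.166 for Hoxd13 and 0.0977 for Hoxa11, and without tumor 1 it was 0.0589 for Hoxd13. In the Müllerian and steroid receptor list, which holds these genes, 7 of 28 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.117, fry 0.533), and without tumor 4 the list passed (8.5e-05, higher). Amhr2, the receptor of the anti-Müllerian hormone, fell by 1.67 ± 0.43, Lhx9 fell by 2.23 ± 0.42, and Greb1, an estrogen target, fell by 1.23 ± 0.39. The call of Greb1 was lost without any 1 of oviducts 1, 2, 3 and 5 or tumors 2 and 4 (adjusted p up to 0.0933). Esr1, the estrogen receptor, changed by -0.77 ± 0.21 (adjusted p = 0.0199), under the minimum of log2 1. Pgr was at 1219 ± 546 and 863 ± 419 (adjusted p = 0.28).

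Genes of skeletal muscle, cartilage, bone and nerve did not move as groups by camera. Of 23 skeletal muscle genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.179, fry 0.516). The list passed without tumor 4 (0.0416) and without tumors 1 and 4 (0.00747), but without tumor 2 its median change went from 0.41 to -0.16 (adjusted p = 0.85). Its mean (log2) was 6.668 in tumor 2 and 4.798 to 5.161 in the other tumors. Eya1, Chrna1 and Myog rose, and the embryonic myosin Myh3 was at 409.9 in tumor 2 and at most 3.4 in any other library. Myog, the myogenic factor, had no read in the oviducts and 38.7 ± 53.5 in the tumors, at least 11.5-fold higher than the floor of 3 counts per library, and at least 3.9-fold without tumor 2. Its call (adjusted p = 0.0265) was lost without any 1 of the 5 oviducts or tumor 3 (adjusted p up to 0.0589), and that of Eya1 without tumor 1 (0.0509). Of 20 cartilage genes 6 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.559, fry 0.918). Matn4, a cartilage matrix protein, rose by 3.75 ± 0.51 and Col11a1 by 2.57 ± 0.28. Sox9, the chondrogenic factor that epithelia also express, fell by 2.21 ± 0.28, and Chad fell by 3.42 ± 0.34. Col2a1 rose by 2.85 ± 0.92 (adjusted p = 0.0385), with 867.2 in tumor 1, and lost its call without any 1 of the 5 oviducts or tumor 3 (adjusted p up to 0.0787), as did Col9a2, which also lost it without tumor 1 or 2 (up to 0.0955). Of 10 bone genes 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.182, fry 0.00255, higher, adjusted p = 0.401 with an estimated correlation). Those that rose were Col1a1 and Dlx5. Those that fell, Sost and Omd, both lost the call without any 1 of oviducts 1, 2 and 3 or tumors 2 and 3, as did Sost without oviduct 4 or tumor 4 and Omd without oviduct 5 (adjusted p up to 0.0924). Of 17 neural genes 3 rose and 3 fell, with 5 and 3 adjusted over the list alone (camera adjusted p = 0.179, fry 0.14). The calls of Elavl4 (higher) and Map2 (lower) were lost without any 1 of the 5 oviducts or tumor 3, of Elavl4 also without tumor 1 and of Map2 without tumor 2 or 4 (adjusted p up to 0.0917). Sox11, an embryonic SOX factor, rose from 3.73 ± 3.68 to 1933 ± 1676.

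Macrophage, endothelial and immediate early genes were higher in the tumors. Of 20 macrophage genes 14 rose (15 adjusted over the list alone) and 0 fell (camera adjusted p = 1.33e-06, fry 0.0273, adjusted p = 0.401 with an estimated correlation). The list mean (log2) of tumor 3, 8.106, was close to that of the highest oviduct, 8.1, while the other tumors had 8.958 to 10.686. Lyz2, the lysozyme of macrophages and neutrophils, rose from 1733 ± 512 to 14207 ± 10356. Of 19 endothelial genes 11 rose and 0 fell, and adjusted over the list alone 11 rose and 1 fell (camera adjusted p = 5.72e-06, fry 0.00787, adjusted p = 0.397 with an estimated correlation). Cdh5, the endothelial cadherin, rose by 2.15 ± 0.25 and Eng by 1.83 ± 0.37. Of 19 immediate early and dissociation response genes 11 rose and 1 fell, with 13 and 1 adjusted over the list alone (camera adjusted p = 5.72e-06, fry 0.0179, adjusted p = 0.401 with an estimated correlation). Fosb rose by 4.73 ± 0.69, Fos by 3.67 ± 0.58 and Egr1 by 2.90 ± 0.41, while Hsph1 fell by 1.72 ± 0.40.

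Markers of other tissues varied between libraries, and some were by far the highest in 1 library. Of 13 fat cell genes 0 were called (camera adjusted p = 0.228, fry 0.472). Adipoq stood at 5427.6 normalized counts in tumor 4, at 0.0 in the other tumors and at 224.4 to 1703.7 in the oviducts. Without tumor 4 the fat cell list passed, with an adjusted p of 3.36e-06, lower in the tumors. Of 9 red cell genes 0 were called (camera adjusted p = 0.142, fry 0.472), and Hbb-bs stood at 32048.4 in tumor 1 against at most 1254.8 elsewhere. Of 16 ovarian steroid genes 3 fell, also adjusted over the list alone (camera adjusted p = 0.0832, fry 0.056, 0.00793 without oviduct 3, and 0.0277 with a block by replicate number). Hsd3b1, a steroidogenic enzyme, fell from 2172 ± 3318 to 0.243 ± 0.486, and Cyp11a1 fell by 5.21 ± 1.32. Both were highest in oviduct 1, at 8035.8 and 13134.8. Oviducts 2 to 5 held 72.6 to 1435.9 of Hsd3b1 and 23.9 to 1191.6 of Cyp11a1, and no tumor held more than 1.0 and 27.3. With limma-voom the adjusted p of Hsd3b1 and Cyp11a1 were 0.09 and 0.24. Of 10 oocyte genes 0 were called (camera adjusted p = 0.506, fry 0.437), and of 20 T and NK cell genes 0 (camera adjusted p = 0.363, fry 0.819). For the fat cell, red cell, oocyte and T and NK cell lists the count adjusted over the list alone was also 0. Of 15 B and plasma cell genes 1 fell and 0 adjusted over the list alone (camera adjusted p = 0.931, fry 0.872), and that gene, Pax5, lost its call without any 1 of oviducts 1, 2, 3 and 5 or tumors 1, 3 and 4 (adjusted p up to 0.0967). Of 20 hypoxia and glycolysis genes 1, Hk2, rose (0 adjusted over the list alone). That list did not pass (camera adjusted p = 0.0766, fry 0.532), but did without tumor 3 (0.00015), tumor 2 (0.0288) or oviduct 4 (0.0453) and with a block by replicate number (0.0271). Without tumor 1 its median change went from 0.56 to 0.13 (adjusted p = 0.636), and without tumors 1 and 4 its direction turned to lower (0.14).

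By camera with a preset correlation 12 of the 26 lists passed, by fry 12, and with an estimated correlation 0. Among the largest single rises outside these groups, Spp1, which codes for osteopontin, rose from 367 ± 645 to 19791 ± 17541, and Prap1, a secreted protein of the pregnant uterus, from 97.1 ± 103 to 24780 ± 40177. Oviduct 4 held 1520.2 of Spp1 and the other oviducts 54.7 to 114.5, and tumor 2 held 85004.6 of Prap1 and the other tumors 2720.6 to 6242.5. Capn6 rose by 4.86 ± 0.77. The neutrophil genes S100a8 and S100a9 and the neutrophil-attracting chemokine Cxcl5 rose by 5.10 ± 1.24, 5.83 ± 1.13 and 5.03 ± 1.29, and Chil1 and Kap by 4.70 ± 1.09 and 4.62 ± 1.31. S100a9 stood at 4316.3 in tumor 2 and 3675.5 in tumor 4, and at 25.9 in tumor 3. With limma-voom the adjusted p of these 5 genes lay between 0.122 and 0.21.

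**Figure D2:**
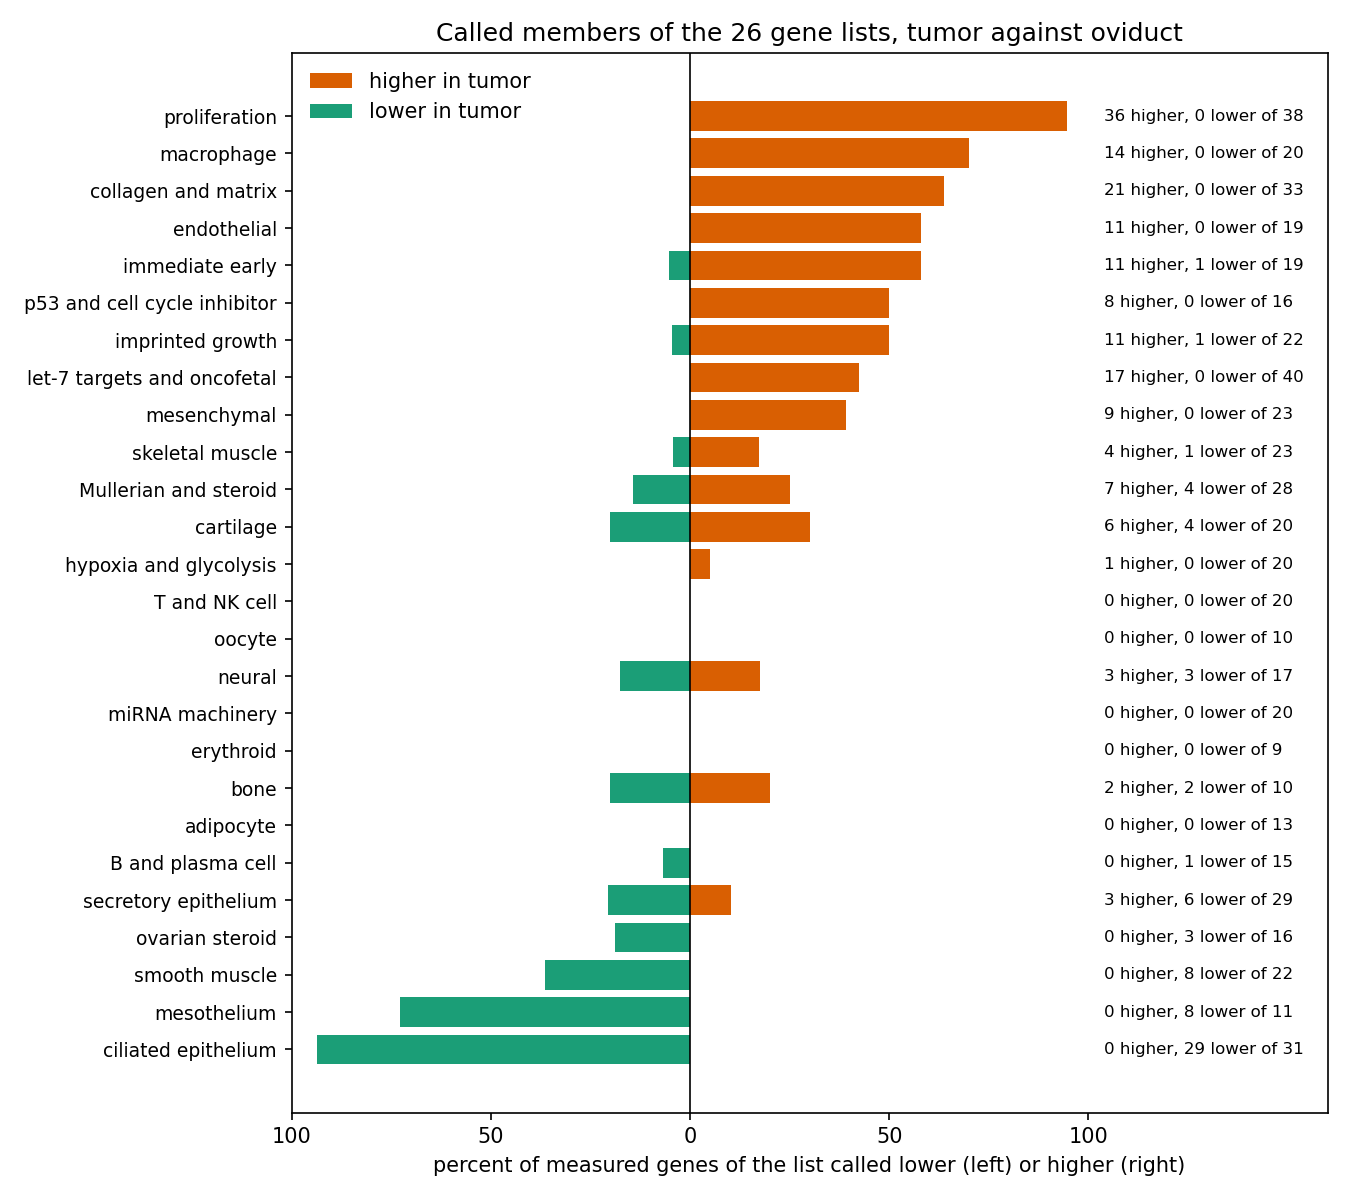
Percent of the measured genes of each of the 26 lists that were called higher (orange, right) or lower (green, left) in the 4 tumors than in the 5 oviducts, with the counts in text. Proliferation has 36 of 38 genes higher and ciliated epithelium 29 of 31 lower.

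Genes with miRNA sites were compared because D1693N lies in the domain that frees 5p strands. Genes with a let-7 site in the 3' UTR (1843 of 16332) had a log2 change that was larger by 0.037 ± 0.029 (SE) than that of genes without one, after adjustment for UTR length and GC content. This was under 2 standard errors, although 96.3% of the 7-mers compared had a lower rank. Most 7-mers lay below 0, since the miR-23 site, with a coefficient of 0.0, already ranked above 74.6% of them. The coefficient was 0.024 without tumor 1 and 0.068 with limma-voom. The 11 families of 5p strands and the 16 families of 3p strands did not differ, with a mean 5p coefficient minus 3p coefficient of 0.007 (two-sided permutation p = 0.7045), which was 0.003 without tumor 2 and 0.015 without tumor 3. The largest coefficients were those of 3p families: miR-29 with 0.104 ± 0.025 (rank 6 of 16049 7-mers) and miR-200b and miR-200c with 0.082 ± 0.026 (rank 20). The 5 sites ranked above miR-29 were rich in T or A, TTTTTAA among them. The lowest coefficient was that of the 5p family miR-21, -0.108 ± 0.033. Genes are not independent replicates, so these errors describe differences across genes in the same 9 libraries.

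**Figure D3:**
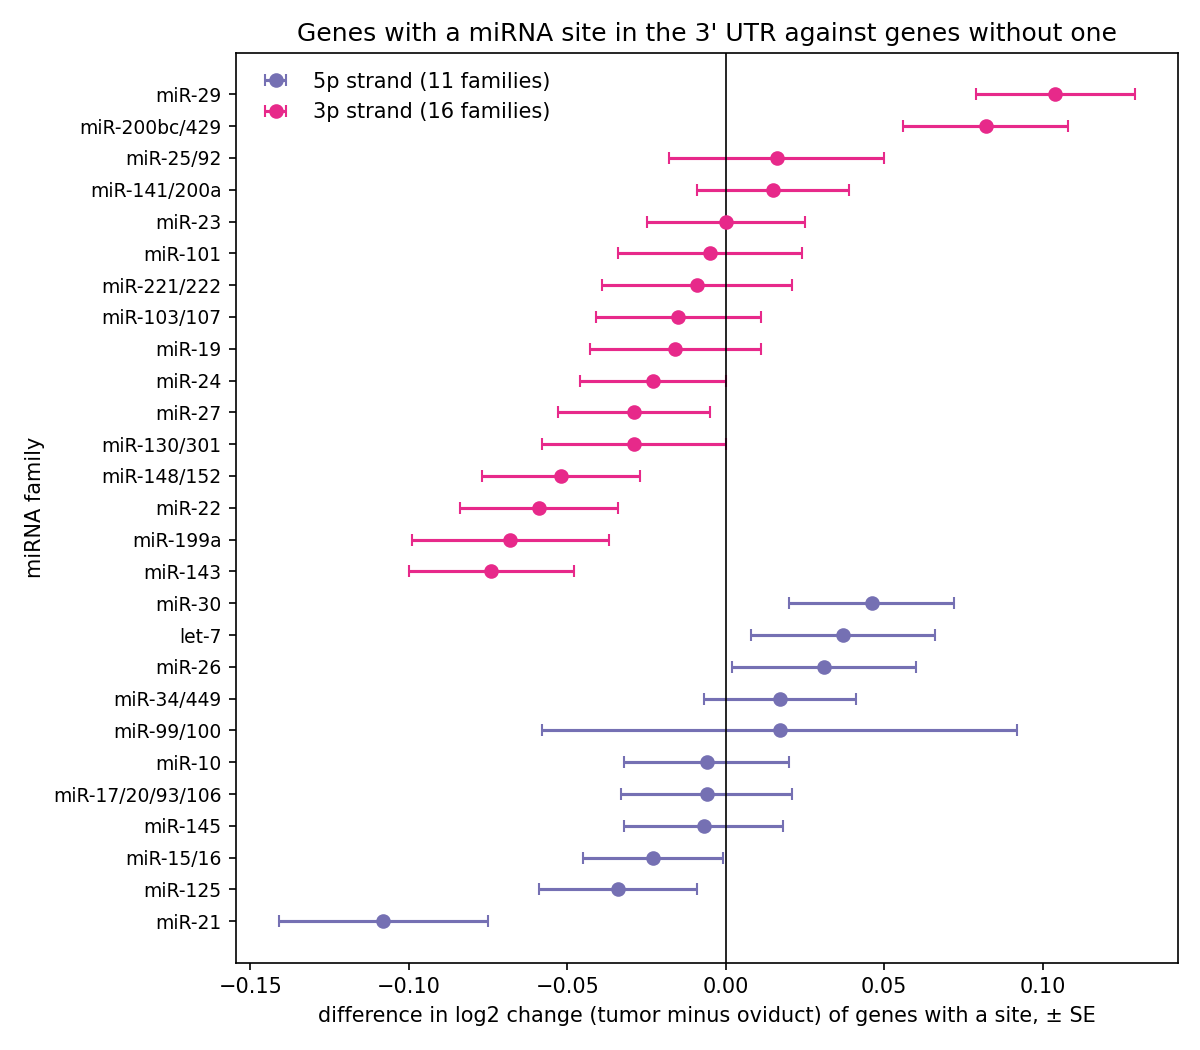
Difference in log2 change (tumor minus oviduct) between genes with and without a site for each of 27 miRNA families, adjusted for 3' UTR length and GC content, with bars of ± 1 SE. The 3p families miR-29 (0.104) and miR-200b and miR-200c (0.082) lie farthest to the right and the 5p family miR-21 (-0.108) farthest to the left.

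The tumors were also compared with the 3 Dicer1+/D1693N oviducts, which carry the same D1693N allele beside a normal one. Relative to these, 1004 genes were called higher and 2219 lower. Prap1 rose by 7.09 ± 1.04 (adjusted p = 0.00139), Spp1 by 6.95 ± 1.10, H19 by 6.24 ± 0.93, Sox11 by 5.98 ± 0.99 and S100a9 by 5.84 ± 1.37. The ciliary genes Dnah5, Ccdc108, Ccdc153 and Dnah3 fell, with changes of -7.93 ± 0.72, -7.69 ± 0.75, -7.50 ± 0.69 and -7.10 ± 0.80, and Sec14l3 fell by 8.12 ± 0.25. Without oviduct 1, 2 or 3 the number of higher genes was 641, 618 or 582, and with array weights it was 1538. Without the minimum change it was 1691.

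Against the 2 Dicer1+/+ oviducts, which carry no Dicer1 mutation, 791 genes were called higher and 1892 lower in the tumors. Prap1 rose by 5.99 ± 1.18 (adjusted p = 0.00877), H19 by 5.91 ± 1.05, S100a9 by 5.82 ± 1.55, Sox11 by 5.81 ± 1.12 and Spp1 by 5.08 ± 1.25. Dnah5 fell by 7.96 ± 0.82 (adjusted p = 0.000303) and Sec14l3 fell by 7.80 ± 0.28. Ccdc153, Ccdc108 and Dnah6 fell too, with changes of -7.49 ± 0.78, -7.19 ± 0.84 and -7.08 ± 0.59. Without oviduct 4 the counts were 327 higher and 1075 lower, without oviduct 5 they were 218 and 905, and 1314 genes were higher without tumor 4. Array weights gave 1193 higher genes.

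The 3 Dicer1+/D1693N oviducts and the 2 Dicer1+/+ oviducts were compared to see whether the control genotypes differ. In the 3-group model 4 genes were called. That model shares 1 spread over all 9 libraries, and the tumors varied more than the oviducts. Differences between the oviducts can therefore be missed, and the low count does not show that the genotypes are alike. For a gene that hardly varies among the tumors, the shared spread can instead be too small and favor a call. Dcpp2, 1 of the 4, had no read in any tumor. Ighg3, the constant region of an IgG heavy chain of plasma cells, rose by 4.73 ± 0.49 in the Dicer1+/D1693N oviducts, with 233.3 to 770.4 normalized counts against 3.1 and 4.5 in the Dicer1+/+ oviducts. The B and plasma cell list means (log2) were also higher, 6.887 to 8.716 against 5.79 and 6.592, as were those of T and NK cells, 5.105 to 5.91 against 4.665 and 4.838. The cartilage, red cell, let-7 target and miRNA machinery list means were likewise higher in all 3 than in both Dicer1+/+ oviducts. Those of hypoxia and proliferation were lower in all 3. The B and T cell lists therefore do not stand out, and no list was tested between the genotypes. Wfdc18 fell by 3.40 ± 0.35, from a mean of 1986 in the Dicer1+/+ oviducts to 173, and Slc6a2, the noradrenaline transporter, fell by 3.29 ± 0.33, from 722 to 55.5. Dcpp2 fell by 3.5 ± 0.36, with 183.9 and 77.0 in the Dicer1+/+ oviducts and at most 2.2 in the others. The adjusted p of all 4 was 0.0212, and an unadjusted p under 0.05 was seen for 237 genes higher and 297 lower. With the 5 oviducts alone these were 1423 and 1432, with 0 genes called, and with array weights 846 and 1010. The counts fell to 0 higher and 0 lower without oviduct 2, 3, 4 or 5 or tumor 1 or 2, to 1 and 0 without oviduct 1 and to 0 and 2 without tumor 3. They were also 0 and 0 with log2(normalized count + 1), and 0 and 2 with limma-voom.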

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

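Of the tests below, those of fewer epithelial cells, of squamous epithelium, of smooth muscle and of other splits of the libraries for gene counts were chosen after the results they measure were seen. The other splits asked whether a random grouping of the libraries gives as large a result. The real split of the 9 libraries called 3625 genes, and as large a count arose in 1 of 100 drawn splits (the real one). The highest other split gave 866, so a random grouping is an unlikely source of the count. The real split is always among those drawn, so 1 is the lowest possible result. The splits do not tell what differs between the groups. For tumors against Dicer1+/D1693N oviducts, 1 of 35 splits gave as many as the real 3223 genes, and the highest other gave 1141. For the gene lists tested by camera, 60 of 100 splits gave at least the 12 lists of the real split, with up to 20, so chance cannot be excluded for that count. By fry, 1 of 100 splits gave as many as 12 lists, and the highest other gave 4.

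Ciliated genes fell by more than general epithelial genes, where a general loss of epithelial cells would lower all of them about alike. The 16 general epithelial genes, all expressed in the oviduct and all also in other lists, had a median change of -0.379 (quartiles -0.809 and -0.085), against -4.99 for the ciliated list, which argues against fewer epithelial cells of every kind as the whole of it. The 16 genes do not tell normal oviduct epithelium from the tumors' own, so a loss of the normal epithelium was not tested. A partial loss of epithelial cells of every kind also stays open. Of the 16, 6 passed as lower, Cdh1 (-1.01) and Spint2 (-1.15) among them, and 1 as higher (Cldn4). The set means of tumors 1 and 3, 9.805 and 9.509, lay below the lowest oviduct (10.358). Epithelium of the uterus in the tumor samples was tested on 6 measured uterine genes. The outcome set in advance against it, a median change of 0 or below, was met (median -0.45). A further condition was added later, because 4 of the 6 are also expressed in the oviduct. By it this epithelium cannot be told apart from the tumors' own epithelium, and Foxa2 (-3.23) and Lif (0.75) went opposite ways. The Dicer1 genotype and the tumor state both stay open. They cannot be told apart, since all tumors and no oviduct were Dicer1ko/D1693N, and no normal tissue of that genotype was sequenced.

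Hoxa10, Hoxa11, Hoxa13 and Hoxd13 were higher in tumors 1 to 3 than in every oviduct, and Hoxa10 in tumor 4 too. Squamous epithelium of the cervix or vagina would bring Krt5 and Krt14 with these genes. In tumors 2 and 3, however, Krt5 stood at 0.0 and Krt14 at most at 0.012 of the Hoxa13 count (median of the 2 at most 0.006), which argues against it there, although Krt14 in tumor 3 (23.6 normalized counts) exceeded the oviducts (6.6 ± 4.4). The bound first set, both keratins below the Hoxa13 count, was met in tumor 1 too (0.452 for Krt5), but Krt13 at 257.4 against 37.1 ± 11.4 in the oviducts leaves room for such cells, and by a bound of 0.1 on the median ratio, set after the values were seen and used for muscle too, this source cannot be told apart there (0.268). Smooth muscle of the lower tract is argued against in tumor 3, where Myh11, Actg2 and Cnn1 stood at 0.186, 0.026 and 0.031 of the Hoxa13 count (median 0.031) and the list mean minus that of the lowest oviduct was -2.214 (log2), but cannot be told apart in tumors 1 and 2, where the median ratio was at least 2.067 and that difference 0.133 and -0.737. The Dicer1 genotype and the site in the tract from which each tumor grew, which the labels give only as oviduct, stay open and were not tested.

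Genes with a miR-29 site were higher in the tumors. This site was singled out among 27 families, and 46 of 100 splits gave a largest coefficient over its SE at least as large as its 4.107 (highest other 6.59), so chance cannot be excluded. Without 68 collagen, laminin and matrix genes, 30 of them with a site, the coefficient was 0.082 ± 0.025, so these genes did not make up all of its size. That error describes differences across genes, and the splits reached larger values over their SE. Whether the remainder exceeds chance can therefore not be told. Base composition beyond the UTR term and cell composition stay open, and miRNAs were not analysed here.

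The let-7 coefficient of 0.037 was reached by 1 of 100 splits (the real one), with 0.036 in the highest other. Splits that mix tumors with oviducts hold less of the difference between them, so this result is no evidence for let-7 itself. The coefficient was also under 2 standard errors (SE 0.029). The difference between 5p and 3p families, 0.007, was reached by 39 of 100 splits (highest other 0.017).

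Of 290 groups of values tested, 26 had a library that stood far from the others. The limit used gives 5%, about 14.5, for normally distributed values. Ccdc153, Cdhr3, Lrrc74b, Rsph4a and Lect1 had 0.0 in all other tumors, where any read is flagged, so the 26 cannot be set against chance. Of the flags, 11 were in tumor 1, 7 in tumor 4 and 8 elsewhere, and genes of 1 cell type are not independent. Tumor 1 kept more ciliary signal than the other tumors: Ccdc153 was at 67.0 normalized counts, Ccdc108 at 98.1, Cdhr3 at 27.2, Lrrc74b at 7.8, Rsph4a at 26.2 and Dnah12 at 112.7, where the other tumors had at most 1.1, and the ciliated list mean was 6.364 (log2) against at most 5.021. Tumor 1 also stood apart for Lin28b (538.0), Igf2bp3 (409.8), Hsph1 (238.9, against at least 962.6) and the red cell list mean (10.026, against at most 6.119). Tumor 4 was low for Ovgp1 (111.5), Cdkn2a (135.7), Matn4 (61.0) and Mest (204.0). It was high for the fat cell list mean (11.623, against at most 4.983) and the mesothelial list mean (8.305, against at most 7.343). Lect1 was flagged in tumor 4 at 4.2, near the floor, against 0.0. Among the oviducts, oviduct 4 was high for Spp1 (1520.2), Ovgp1 (150619.1) and Lox (628.8) and low for Greb1 (1374.8). Oviduct 5 was high for Pgr (2186.0) and low for Nt5e (96.0), and oviduct 3 was high for Egr1 (924.4) and low for the imprinted list mean (7.033, against at least 7.221).

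The 2 control genotypes differed in 4 genes by limma, with log2 changes (Dicer1+/D1693N minus Dicer1+/+) of 4.73 for Ighg3, -3.5 for Dcpp2, -3.4 for Wfdc18 and -3.29 for Slc6a2. The direction held in all 3 against both oviducts, which adds no support, since the genes were picked by this same contrast. With the 5 oviducts alone 0 genes were called, as with log2(normalized count + 0.25) and log2(normalized count + 1) and without oviduct 2, 3, 4 or 5 or tumor 1 or 2, and without oviduct 1 or tumor 3 the counts were 1 higher and 0 lower or 0 and 2, so the calls depend on these choices.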

How the results depend on the processing

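Leaving out tumors 1 and 4, the 5 oviducts alone, limma-voom and log2(normalized count + 1) were chosen after seeing the data. The planned count-model test on whole reads was not run, and limma-voom on the recovered reads took its place (1247 higher, 2958 lower in the tumors). Of the counts of called genes under alternatives, 134 stayed within 1.5 times the main count and 36 did not. For tumor against oviduct these were 2446 higher and 3605 lower without a minimum change, by construction, and 358 and 1178 with the Dicer1+/+ oviducts alone, a smaller sample. A block by replicate number gave 1034 and 2196, and without tumors 1 and 4 the counts were 1568 and 2723. Against the Dicer1+/D1693N oviducts the higher genes numbered 1691 without a minimum change, 1538 with array weights and 582 (without oviduct 3) to 1416 (without tumor 4) when 1 library was left out. Against the Dicer1+/+ oviducts they numbered 1193 with array weights and 218 (without oviduct 5) to 1314 (without tumor 4), with 905 to 2256 lower. Between the oviduct genotypes the counts were 0 higher and 0 lower with log2(normalized count + 0.25), log2(normalized count + 1) and the 5 oviducts alone, 0 higher with limma-voom, and 0 to 1 higher and 0 to 3 lower when 1 library was left out; for array weights and these, the cause was not tested. With an estimated correlation 0 lists passed. The sign of the B and plasma cell list turned by fry (adjusted p = 0.872), by quantile normalization (0.977), with the block (0.743) and without oviduct 1, 4 or 5 or tumor 2 or 4 (0.49 to 0.949), where the range over each library left out was 0.367 to 0.949. That of T and NK cells turned without tumor 2 (0.62; range over each library left out 0.122 to 0.631), that of cartilage by fry (0.918), and those of hypoxia (0.14) and oocyte genes (0.795) without tumors 1 and 4. None of these turned lists passed, and the cause was not tested. Dicer1 ranged from -0.39 (without tumor 3) to 0.02 (without tumor 4). Ighg3 changed by 0.66 against the Dicer1+/+ oviducts alone, which had little of it. Igf2bp3 changed by -0.11 without tumors 1 and 4 and by -0.09 (without tumor 1) to 1.02 (without tumor 2), since tumor 1 held most of it, and Pgr by 0.05 without tumors 1 and 4, the cause not tested. The let-7 coefficient was 0.045 by the number of sites, where it passed 2 standard errors. Of 114 named genes past the threshold, 6 to 13 were lost without 1 library, 15 with limma-voom, 30 with the Dicer1+/D1693N and 54 with the Dicer1+/+ oviducts alone. With the block by replicate number 12 were lost, Cldn4 (limma adjusted p = 0.06) and Esr1 (0.0794) among them, and without tumors 1 and 4 it was 9. Depth limits genes near the floor of 3 counts per library. In simulated data, which held no changed genes near the floor, 16.4% of 2-fold changes were called. Their median estimate was 0.93, under the minimum of log2 1.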

Other observations

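The genes of this part were singled out after their values were seen. Among 10 Hox genes of paralog groups 10 to 13, 7 rose, Hoxa13 and Hoxd13 included, and 0 fell. Among 26 genes of groups 1 to 9, 1 rose (Hoxb9, by 1.81) and 10 fell, with changes of -2.63 for Hoxa5, -2.7 for Hoxc4, -2.51 for Hoxc6 and -2.04 for Hoxa3. Hoxd12 had no read in the oviducts and 248.6, 82.9, 1119.1 and 0.0 normalized counts in tumors 1 to 4, a mean at least 108.3-fold higher than the floor of 3 counts per library, and at least 33.0-fold without tumor 3.

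Sprr2f, a small proline-rich protein under estrogen control, rose by 4.20 (adjusted p = 0.00857), with 97.1 to 2858.2 normalized counts in the tumors and 4.5 to 78.2 in the oviducts. Guca2b, which codes for uroguanylin, rose by 3.36 (adjusted p = 0.0191) and was highest in tumor 2, at 22624.1. Lcn2 and Ltf, secreted antibacterial proteins, did not pass (adjusted p = 0.0709 and 0.25). Ltf stood at 88000.2 and 94984.2 in tumors 2 and 4, at 4585.7 in tumor 3 and at 5651.5 to 25109.0 in the oviducts. Dcx, a gene of migrating neurons, stood at 1148.4 in tumor 3 and at 0.0 in tumor 4 (adjusted p = 0.0547). Lin28a, which like Lin28b blocks let-7 maturation, rose by 2.62 (adjusted p = 0.00737), with 226.3, 20.4, 118.2 and 8.4 in tumors 1 to 4 and at most 1.6 in the oviducts.

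Fuom, on the minus strand, overlaps the end of Prap1 on the plus strand by 431 bp (GRCm38 chromosome 7, 140096770 to 140097200) and rose by 3.76. The ratio of Fuom to Prap1 was 0.833, 0.826, 0.743 and 0.79 in tumors 1 to 4, where the oviducts had 2.763 to 12.409. Whether reads of 1 gene were counted for the other was not tested, and the use of the strand in counting is not stated.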
